A study of Mus musculus with 32 samples.

How the data were processed

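The series holds 32 arrays with 2 channels, and each array was read 3 times, giving 96 scanner tables. Per the file headers, each table gives the authors' deposited intensity of a spot in channel A and in channel B, corrected for background, and the local background, with quality flags. The software that corrected the background is not given in the sources used here. The deposited series table holds a score per spot, the authors' log ratio, whose log base and normalization are not stated. Set against print-tip loess values computed here, its columns had medians of -0.0116 to 0.0068, correlated with log2 of channel B over channel A with the sign of the labelled dye on all arrays, and ran with slopes of up to 1.03 in size, so that its centring is near 0 and its base stays unknown. The dye read by each channel is not stated, and channel B was taken as Cy5 on this basis. Per the labels, 2 arrays of opposite dye label make up each total RNA replicate. The series' design gives 4, 5 and 6 biological replicates for 18 h, 72 h and 192 h, while the titles number 4, 4 and 6.

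The 3 reads of an array were treated as repeat scans of 1 slide, since their log ratios correlated between 0.53 and 0.98. Spots with an intensity of 0 or below in either channel were left out, which leaves out the spots flagged as not found. Intensities were already background corrected, so no further correction was applied. Log2 ratios were normalized within each read by loess with spots of no listed gene at weight 0, averaged over the reads and over spots of one accession, and turned to tumour over PBS by the labelled dye. A total RNA replicate is the mean of its 2 orientations and is missing when either is missing. A probe was tested when it had a value in all 8 replicates. The planned filter on dim probes asked for a foreground over 1.5 times the background in at least 1 channel and 1 read on 50% or more of the 16 arrays, since the tables hold no background SD. It removed 0 of the 9008 accessions, so it had no effect. Of these accessions 1008 were tested. Each array design listed 12 spots with several gene symbols, which were not named, and 994 or 1002 spots without a listed gene. Symbols were checked through gene identifiers against the RefSeq table of GRCm38.p6, where 8977 or 8985 listed spots per design matched and 0 symbols changed. No genome build is named for the arrays and no coordinates are given.

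Values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), with the time as group, no covariate, and Benjamini-Hochberg adjustment over probes at 0.05. The contrasts were each time against 0, the mean of the times, and an F-test of the differences between times. All times share one estimate of the spread. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with the brightest probe per gene, on lists with at least 5 measured genes, and also with an estimated correlation and with fry. There were 34 lists, of which 11 are cell type markers, fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. The rule for named genes took the called genes of largest change, or, where fewer than 5 passed, the 10 named probes of smallest p as values, 10 for the difference between times, 2 members per described list, and Npy, Agrp, Pomc, Cartpt, Crh, Avp, Oxt, Hcrt, Pmch, Trh and Fos. On data simulated with the spread of the 1008 probes, with 200 changed probes, the fit called 70.2% of probes changed by a log2 ratio of 0.5 and 98.2% of those changed by 1 at 18 h, 70.0% and 98.5% at 72 h, and 92.1% and 99.4% at 192 h. The simulated noise was independent and normal, was drawn from limma's moderated spread, and holds neither single-array artefacts nor a dye effect. Benjamini-Hochberg adjustment is stricter where fewer probes change. These rates therefore hold only for such noise with 200 changed probes of 1008, and overstate what the fit would call if few changed. The simulated replicates also had equal spread, whereas the real ones had SDs of 0.154 to 0.449 over the tested probes. The rates may thus not apply to these data.

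Batches in the files are the array designs. Each of the 2 total RNA designs holds all times, and fits with the design as a covariate and within each design were run. Identity of spots between designs was checked by the brightness of each accession. Alternatives were other background corrections, normalizations, filters, single reads, the polyA arrays, arrays one by one with duplicateCorrelation, array weights, the replicate number as a block, leaving out each replicate, and the authors' values. Sets of probes with fewer replicates, in which the inter-gene correlation was estimated from residuals and taken as no lower than the preset one, and a fit with unturned ratios were added after seeing the data. Figures were drawn with matplotlib 3.10.9.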

Results

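The arrays compared RNA of the hypothalamus of C57Bl/6 male mice aged 8 weeks after a subcutaneous injection of 1000000 LL/2(LLC1) cells, a Lewis lung carcinoma line of mouse origin, in 300 µl of phosphate-buffered saline (PBS) with that of mice given 300 µl of PBS alone. Tissue was taken 18 h, 72 h or 192 h after the injection, and RNA of a tumour-injected and of a PBS-injected source was hybridised against each other on each of 32 printed oligonucleotide arrays with 2 dyes. The question was which transcripts differ in the hypothalamus of tumour-injected mice at each time. By their titles 16 arrays held polyA RNA (replicates 1 and 2 of each time) and 16 held total RNA (replicates 3 and 4 at 18 h and 72 h, and 3 to 6 at 192 h). Each total RNA replicate had 1 array per dye orientation, whereas all polyA arrays of 18 h and 72 h were labelled with tumour RNA in Cy5. The series' design text instead gives dye-swapped technical replicates throughout, and it stays open whether title numbers 1 and 2 of these polyA arrays mark samples or dye orientations; the labels were followed. The comparisons therefore rest on the 8 total RNA replicates, 2 at 18 h, 2 at 72 h and 4 at 192 h. The labels do not say how many animals stand behind a replicate, so p-values measure only the spread between these samples. Between 3608 and 8395 of the 9008 listed probes gave a ratio on a total RNA array. The number of arrays limits the precision.

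The 2 layouts of the total RNA arrays place the same probes at different spots, and spots of ribosomal protein genes were bright on both, at a mean brightness percentile of 92.3 and 89.6, while those of olfactory and vomeronasal receptor genes lay at 29.6 and 33.0. On 15 of the 16 polyA arrays this order was missing. Ribosomal protein genes lay at a mean percentile of 49.7 on the design with 11 polyA arrays and 44.5 on the design with 4, and the receptor genes at 54.4 and 54.5. The rank correlation of brightness over listed genes with the total RNA arrays was 0.047 to 0.112 on these 15 arrays, 0.658 on the remaining polyA array, and 0.293 to 0.681 for each total RNA array against the other layout. These correlations are across genes, which are not independent replicates. The gene names listed for the spots of those 15 arrays were thus not borne out by the values, and no gene is named from them.

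**Figure D1:**
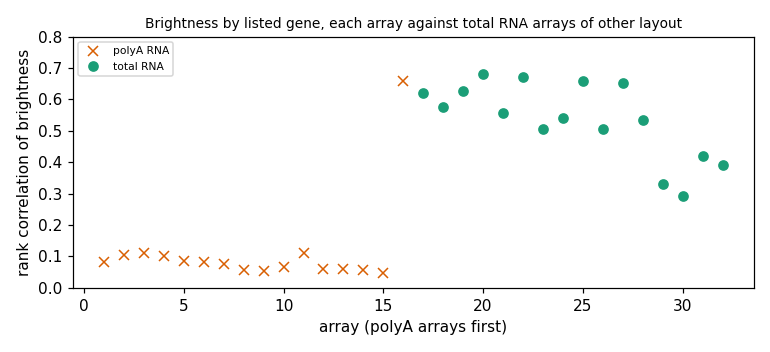
Rank correlation across listed genes (vertical axis, no unit) between the brightness of 1 array and that of total RNA arrays, for 16 polyA arrays (crosses; against the mean of both total RNA layouts) and 16 total RNA arrays (circles; each against the layout it does not have), in array order. 15 polyA arrays lie between 0.047 and 0.112, and the remaining one at 0.658.

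No gene passed an adjusted p of 0.05 in the hypothalamus at any time, among the 1008 probes of 1004 genes measured in both dye orientations in all 8 replicates. Log2 ratios are given as tumour over PBS. This direction is likely rather than certain, because the files do not say which scanner channel read which dye: channel B was taken as Cy5, since the authors' deposited log ratios follow channel B over channel A on arrays labelled with tumour RNA in Cy5 and the inverse on the others. If that assignment is wrong, every sign turns alike. The median half-width of the 95% interval of a log2 ratio was 0.30 at 18 h, 0.30 at 72 h, 0.21 at 192 h and 0.16 for the mean over the times. For 98.1% of the probes at 18 h, 98.7% at 72 h and 98.5% at 192 h the interval lay within a log2 ratio of 1 in either direction. These intervals are for single probes and are not adjusted for the number of probes. They bound a tumour effect only if the arrays of each replicate had opposite orientations, as labelled. In the same orientation, tumour values would cancel in their mean, and this stays open.

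At 18 h, 10 genes with the smallest p had log2 ratios from -1.05 to 0.37, and none passed, with the smallest limma adjusted p at 0.991. Of these genes 9 had a value below 0 and 1 above, and all 10 had the same sign in both replicates. A choice by smallest p favours equal signs over the replicates, here and in the comparisons below, so such counts are no evidence of agreement. Cct8, a subunit of the cytosolic chaperonin, had -0.53 ± 0.13 (SE, n = 2), Psmc5, an ATPase subunit of the proteasome, -0.35 ± 0.12, and Pmpcb, a subunit of the mitochondrial processing peptidase, -0.33 ± 0.11. Lars, the cytosolic leucyl-tRNA synthetase, had -0.41 ± 0.13, Dynlt3, a dynein light chain, -0.34 ± 0.11, Gatad1 -0.54 ± 0.13 and Wdr33, a factor of mRNA polyadenylation, -0.53 ± 0.15. Actrt1, an actin-related protein of testis, had 0.37 ± 0.12. The largest values of the group, Pdia6 (a protein disulfide isomerase of the endoplasmic reticulum) at -1.05 ± 0.35 and Ptpmt1 (a mitochondrial phosphatase) at -0.99 ± 0.28, came mainly from replicate 4, where Pdia6 had -1.91 against -0.19 in replicate 3 and Ptpmt1 -1.72 against -0.25. limma with Benjamini-Hochberg adjustment called 0 probes, and 39 had an unadjusted p under 0.05 where chance gives 50.4. On the array of replicate 4 with tumour RNA in Cy5 Pdia6 had -3.78, Ptpmt1 -3.54, Gatad1 -1.71, Cct8 -1.70 and Wdr33 -1.29, and on its dye-swapped partner -0.04, 0.09, 0.09, 0.28 and -0.29. Replicate 3 alone gave -0.34 for Cct8, -0.26 for Gatad1 and -0.27 for Wdr33. Its arrays had -0.73 and 0.05 for Cct8, -0.35 and -0.17 for Gatad1, and -0.42 and -0.12 for Wdr33. Dynlt3 had -0.86 and 0.24 there and Psmc5 -0.85 and 0.05, and both genes were below 0 on each array of replicate 4. Without replicate 3, 1 probe passed at 18 h, that of Ptpmt1 (limma adjusted p = 0.0287).

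At 72 h, the 10 genes with the smallest p had log2 ratios from -0.34 to 0.48. Max, the partner of Myc proteins, had 0.35 ± 0.11 (SE, n = 2), with 0.29 and 0.40 in the replicates. Herpud1, a gene of the endoplasmic reticulum stress response, had 0.37 ± 0.16, with -0.02 in replicate 3 and 0.77 in replicate 4, and Bysl, a factor of ribosome assembly, had 0.48 ± 0.17, with 0.08 and 0.88. Ddb1, of the DNA damage recognition complex, had 0.26 ± 0.12. Below 0 lay Denr, a translation factor, at -0.34 ± 0.13, Clcn4, a chloride transporter, at -0.31 ± 0.11, Rpp14, a subunit of ribonuclease P, at -0.31 ± 0.14, Rnf7 at -0.28 ± 0.12, Dennd6b at -0.27 ± 0.09 and Mtfr1l at -0.25 ± 0.11. Most of these values came mainly from replicate 4, with -0.01 in replicate 3 and -0.61 in replicate 4 for Rpp14, -0.10 and -0.46 for Rnf7, -0.09 and -0.41 for Mtfr1l, -0.17 and -0.44 for Clcn4, and 0.12 and 0.40 for Ddb1. Within replicate 4 they came mainly from the array with tumour RNA in Cy3, which had 1.78 for Bysl, 1.54 for Herpud1, 0.91 for Ddb1, -1.04 for Rpp14, -0.96 for Rnf7, -0.85 for Mtfr1l and -0.86 for Clcn4. Its dye-swapped partner had -0.02, -0.01, -0.10, -0.17, 0.04, 0.03 and -0.02. Denr had -0.51 in replicate 3 (arrays at -0.57 and -0.45) and -0.17 in replicate 4 (-0.0008 and, with tumour RNA in Cy3, -0.34). Dennd6b had -0.27 in both. Its arrays had -0.32 and -0.23 in replicate 3, and 0.12 and, with tumour RNA in Cy3, -0.66 in replicate 4. None of the 1008 probes passed in limma (smallest adjusted p = 0.999), and 8 had an unadjusted p under 0.05 where chance gives 50.4. The SEs and p-values at 72 h use a spread shared with the other times. Over the tested probes the replicates of 72 h had SDs of 0.156 and 0.201. Those of 192 h had 0.160, 0.449, 0.192 and 0.355. The count of 8 is thus not a property of the 72 h replicates alone.

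At 192 h, with 4 replicates, Nell2, a secreted protein of neurons, had a log2 ratio of -0.28 ± 0.08 (SE, n = 4) and was below 0 in all 4 replicates, although the dye orientations had opposite signs in 3 of them (-1.04 and 0.50, -0.39 and 0.05, 0.11 and -0.63). Serinc3 had -0.21 ± 0.07 and Prkcb, a protein kinase C, -0.34 ± 0.11. Epb41l3, a protein of the membrane skeleton, had -0.35 ± 0.11 and Armc1 -0.30 ± 0.10, also with dye orientations apart. In replicates 3 to 6 the arrays of Epb41l3 had -1.05 and 0.81, -0.90 and -0.32, 0.24 and -0.45, and -1.21 and 0.09. Those of Armc1 had -0.01 and 0.08, -0.66 and -0.04, -0.93 and -0.08, and -1.30 and 0.58. R3hdm2 had -0.59 ± 0.19, with -1.49 in replicate 6 and -0.62 to -0.06 in the others. That replicate joined an array at -2.72 and a dye-swapped partner at -0.26. S100b, a calcium-binding protein of astrocytes, had 0.24 ± 0.08, Ddt, the D-dopachrome tautomerase, 0.20 ± 0.07, Tmem167 0.26 ± 0.08 and Crkl, a signalling adaptor, 0.63 ± 0.19. The value of Crkl was set by replicate 4 at 1.53, against 0.24 to 0.43 in the other replicates, whose arrays had 3.47 and, with the dyes swapped, -0.42. Of these 10 genes 8 had the same sign in all 4 replicates, and Ddt alone was above 0 on each array. None passed in limma (smallest adjusted p = 0.786), 0 of 1008 probes were called, and 47 had an unadjusted p under 0.05.

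Averaged over the 3 times, with all 8 replicates, the 10 genes of smallest p had log2 ratios between -0.25 and 0.19. Lars had -0.25 ± 0.07 (SE, n = 8), Pdhb, a subunit of pyruvate dehydrogenase, -0.17 ± 0.05, Serpinb6a, a protease inhibitor, -0.20 ± 0.07, Dync2h1, a dynein heavy chain of cilia, -0.16 ± 0.05 and Zfand5 -0.18 ± 0.06. Nell2 had -0.17 ± 0.06, Cct8 -0.20 ± 0.07 and Dennd6b -0.15 ± 0.05. Max had 0.18 ± 0.06 and Dmac1, an assembly factor of the respiratory chain, 0.19 ± 0.06. Of the 10 genes 5 kept one sign in all 8 replicates. Among these was Dennd6b, which lay below 0 on each array with tumour RNA in Cy3 (-0.66 to -0.08). On most arrays with tumour RNA in Cy5 it lay above 0 (-0.32 to 0.32). limma called 0 of the 1008 probes (smallest adjusted p = 0.990), with 31 at an unadjusted p under 0.05.

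No gene had a log2 ratio that differed between the times by limma's F-test (smallest adjusted p = 0.998; 0 probes called, 19 at an unadjusted p under 0.05). The values of smallest p belonged to Wdr33, with -0.53 ± 0.15 at 18 h, 0.04 ± 0.15 at 72 h and 0.15 ± 0.10 at 192 h, and to Dynlt3, with -0.34, 0.12 and 0.12. Cox7b, a subunit of cytochrome c oxidase, had -0.25, 0.02 and 0.17, Csnk1a1, casein kinase 1 alpha, -0.26, 0.01 and 0.17, and Kl, the anti-ageing hormone klotho, -0.22, -0.18 and 0.24. Armc1 had 0.15, 0.22 and -0.30, Epb41l3 0.26, 0.09 and -0.35, Tmem167 -0.18, -0.01 and 0.26, Gatad1 -0.54, 0.08 and -0.07, and Cct8 -0.53, -0.04 and -0.03. At 18 h the values of Wdr33, Gatad1 and Cct8 were set mainly by 1 array of replicate 4, and replicate 3 had -0.27, -0.26 and -0.34. The pairwise differences gave 0 called probes each, with 16 at an unadjusted p under 0.05 for 72 h against 18 h, 37 for 192 h against 18 h and 8 for 192 h against 72 h.

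Among the peptide precursors of the hypothalamus, Oxt, the oxytocin precursor, had log2 ratios of -0.02 ± 0.12 at 18 h, -0.04 ± 0.12 at 72 h and 0.21 ± 0.08 at 192 h (SE), with 0.13 to 0.27 in the 4 replicates of 192 h. At 192 h its dye orientations had opposite signs in replicate 3 (-0.21 and 0.75) and replicate 6 (-0.25 and 0.51). Both orientations were above 0 in the other replicates of that time. Pmch, the precursor of melanin-concentrating hormone, had -0.03 ± 0.12, -0.19 ± 0.12 and -0.02 ± 0.09. Avp, the vasopressin precursor, had 0.16 ± 0.49, 0.22 ± 0.49 and 0.93 ± 0.35, and at 192 h the replicates had 0.63, 0.13, 0.31 and 2.65. The highest of these, replicate 6, joined an array at 5.35 and a dye-swapped partner at -0.05. Its spread also enters the SE of Avp at 18 h, where the replicates had 0.04 and 0.28. None of the 3 genes passed the threshold at any time. Cartpt, Hcrt and Trh lacked a dye-balanced value in some replicates. In a set of 3985 probes with at least 5 such replicates, chosen after seeing the data, Cartpt had 0.05 ± 0.12 at 18 h, 0.07 ± 0.12 at 72 h and -0.03 ± 0.09 at 192 h, Hcrt, the orexin precursor, -0.04 ± 0.14, 0.03 ± 0.14 and 0.14 ± 0.11, and Trh, the thyrotropin-releasing hormone precursor, 0.03 ± 0.20, 0.01 ± 0.20 and 0.10 ± 0.12. Fos had a balanced value in 4 replicates, with 0.00 in 18 h replicate 3, 0.25 in 72 h replicate 3, and -0.65 and -0.32 in 192 h replicates 5 and 6. Npy, Agrp, Pomc and Crh were not named for any probe here.

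**Figure D2:**
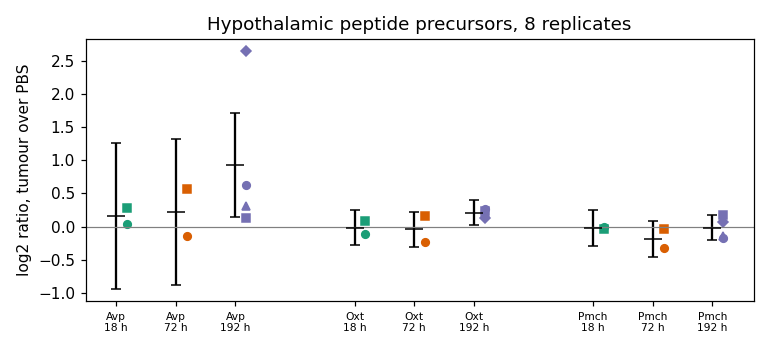
Log2 ratio of tumour over PBS (vertical axis) of Avp, Oxt and Pmch at 18 h, 72 h and 192 h. Bars are limma means with 95% intervals and points are the replicates (circle 3, square 4, triangle 5, diamond 6). The 192 h mean of Avp (0.93) lies above 3 of its replicates because replicate 6 is at 2.65.

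None of the 11 gene lists with at least 5 measured genes was shifted at any time or on average (limma camera, adjusted p over lists). Of 29 genes of oxidative phosphorylation 22 had a log2 ratio below 0 at 18 h, with a median of -0.08 and adjusted p = 0.165, or adjusted p = 0.803 with an estimated correlation. Its members of smallest p were Ndufc1 at -0.25 ± 0.10 and Cox7b at -0.25 ± 0.11. Of 28 ribosomal protein genes 24 lay below 0 at 18 h (median -0.07, adjusted p = 0.263), among them Rpl35 at -0.27 ± 0.12 and Rps7 at -0.24 ± 0.12, and 17 lay above 0 at 192 h (median 0.05, adjusted p = 0.194), among them Rpl36al at 0.24 ± 0.10, with 0.56 in replicate 5 and 0.05 to 0.27 in the others, whereas Rps29 had -0.19 ± 0.10, with 0.10 in replicate 4 and -0.38 to -0.17 in the others. At 72 h the ribosomal protein genes had a median of -0.15 in replicate 3 and 0.16 in replicate 4, and those of oxidative phosphorylation -0.13 and 0.05. Without replicate 4 of 72 h both lists had a negative direction at 72 h, and without replicate 3 the ribosomal list had a positive one. Each of these fits leaves a single replicate at 72 h and takes its spread from the other times, so neither tests 72 h. With median centring in place of loess, both lists passed with negative direction at 18 h, at 72 h and on average, with medians of -0.31 for ribosomal protein genes and -0.35 for oxidative phosphorylation at 72 h, where all tested genes had a median of -0.20, and with an estimated correlation none of these calls held (adjusted p = 0.693 to 0.889).

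The 5 potassium channel genes all lay below 0 at 72 h, with a median of -0.15 and adjusted p = 0.068 (adjusted p = 0.411 with an estimated correlation). The list median was -0.05 in replicate 3 and -0.27 in replicate 4. Kcnma1, a calcium-activated channel, had -0.28 ± 0.16, with 0.02 in replicate 3 and -0.58 in replicate 4, and Kcnmb4, its accessory subunit, -0.16 ± 0.11, with -0.05 and -0.27. The 10 heat shock and unfolded protein genes had adjusted p = 0.093 at 72 h with a median of 0.04, and 5 of them lay above 0, with Herpud1 at 0.37 ± 0.16 and Hsph1, a chaperone, at 0.13 ± 0.11, where Hsph1 had 0.26 in replicate 3 and 0.00 in replicate 4. Under print-tip loess both lists passed, at an adjusted p of 0.0489 each, or adjusted p = 0.341 each with an estimated correlation, and under median centring the median of the heat shock list was -0.12. The 6 proteasome genes all lay below 0 at 72 h (median -0.08, adjusted p = 0.128), with Psma5 at -0.18 ± 0.11 and Psmc4 at -0.13 ± 0.11. In replicates 3 and 4 Psma5 had -0.10 and -0.25, and Psmc4 -0.02 and -0.24. Camera tested 8 neurosecretory hormone genes, with adjusted p = 0.704 at 192 h, where Avp had 0.93 and Pcsk1n, an inhibitor of prohormone convertase 1, -0.19 ± 0.07. The 6 feeding peptides and receptors had adjusted p = 0.651 at 72 h, with Pmch at -0.19 ± 0.12 (-0.33 and -0.04 in the replicates) and Npy2r, a neuropeptide Y receptor, at 0.19 ± 0.15 (0.29 and 0.09). The 5 genes of cholesterol and lipid synthesis had adjusted p = 0.718 at 18 h and 0.317 at 72 h, with Fdft1, squalene synthase, at -0.30 ± 0.12 and Sqle, squalene epoxidase, at -0.16 ± 0.13 at 18 h. In replicates 3 and 4 of 18 h Fdft1 had -0.15 and -0.46, and Sqle -0.28 and -0.04. The 7 oxidative stress genes had adjusted p = 0.427 at 192 h, with Txnrd1, thioredoxin reductase, at 0.21 ± 0.11 (0.05 to 0.42 in the replicates), and the 7 genes of synaptic vesicle release 0.295 at 72 h, with Syt11 at 0.18 ± 0.13. Adjusted over the list alone, 0 genes passed in each of the 11 lists at each time. With an estimated correlation, and by fry, 0 lists passed as well.

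**Figure D3:**
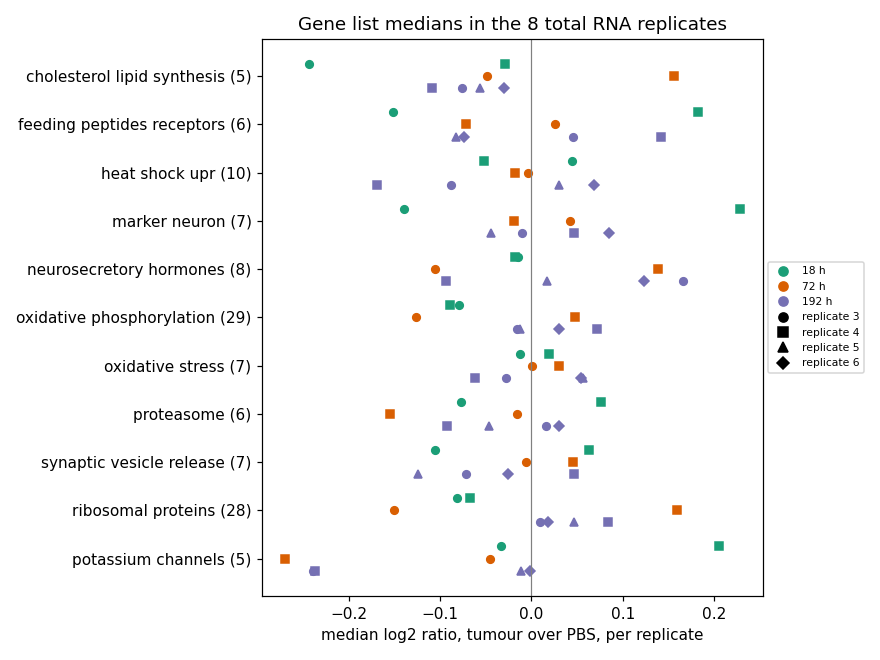
Median log2 ratio of tumour over PBS (horizontal axis) of the genes of 11 lists, with the number of genes in brackets, in each of the 8 total RNA replicates (colour, time; symbol, replicate). The replicates of 72 h lie on both sides of 0 for ribosomal protein genes, at -0.15 and 0.16.

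Of the cell type lists only the neuron markers had at least 5 measured genes. All 7 lay above 0 at 192 h, with a median of 0.09 and adjusted p = 0.240, or adjusted p = 0.880 with an estimated correlation, and without background correction 4 did, with a median of 0.00. Stmn3, a stathmin of neurons, had 0.17 ± 0.10 and Snap25, a protein of synaptic membrane fusion, 0.24 ± 0.27, with 1.16 in replicate 6 and -0.19 to 0.05 in the others. Ncdn, a further member named after its values were seen, had 1.75 in replicate 4 and values below 0 in the other replicates, and the list medians of the 4 replicates were -0.01, 0.05, -0.04 and 0.09. Without replicate 6 the mean of Snap25 lay below 0, and without replicate 4 that of Ncdn, so that the count of 7 rests on single replicates. Of the other lists 3 astrocyte, 2 oligodendrocyte, 2 pituitary and 1 microglia marker were among the tested genes, and 0 of the lymphoid and erythroid markers. Among the 3985 probes with at least 5 replicates, 10 markers of thalamus, cortex and striatum had adjusted p = 0.699 at 18 h, 0.926 at 72 h, 0.750 at 192 h and 0.639 on average, and the lists of 9 astrocyte, 11 oligodendrocyte and 5 ependyma markers did not pass either. No list tested for blood cells.

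The ratio of channel B over channel A, before it was turned by the labelled dye, correlated over probes between the 2 arrays of a replicate with r from -0.14 to 0.77, and above 0 in 6 of 8 replicates, although these arrays carried opposite labels. The mean r was 0.307, against 0.215 over 48 pairs of arrays of different replicates on the same design. In a fit of the 16 arrays 87 of 1008 probes had a dye coefficient past an adjusted p of 0.05, with a median size of 0.11 against 0.08 for the tumour coefficient at 192 h. This fit took the arrays as independent, although they form 8 pairs. The estimated correlation within a replicate was -0.25, so the count of 87 may be too high. After the orientations were averaged, the log2 ratios of the replicates correlated between -0.37 and 0.27 over probes, with a median of 0.01 over 28 pairs, and between -0.24 and 0.12 for replicates of the same time.

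No called gene was there to be followed in the polyA arrays. Across the 1008 probes, as listed, the log2 ratios of total RNA and polyA arrays had r = -0.15 at 18 h, -0.09 at 72 h and -0.06 at 192 h. Since the gene names of 15 polyA arrays were not borne out, and dye and tumour are by their labels confounded there at 18 h and 72 h, these values say nothing about a repeat.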

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

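The tests on the names of the polyA spots were chosen only after the result was seen. Those on the polyA counts were written beforehand. Crkl at 192 h stood apart in replicate 4, with a log2 ratio of 1.53 against 0.24 to 0.43 in the other replicates. Such a value was found in 1 of 52 groups of 4 values, which hold only named genes and list medians and where chance gives about 1 in 20. Over 117 list members, counted after their values were seen, 14 had such a value, 8 of them in replicate 4, with 2.29 for Scd2, 1.83 for Cplx1 and 1.01 for Srxn1. Replicate 4 had the widest spread of the 8 replicates (SD 0.449).

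The polyA arrays, which no comparison of the report uses, gave many probes past an adjusted p of 0.05 in limma with a dye covariate. There were 202 at 18 h, 189 at 72 h, 256 at 192 h and 413 on average, of 5589 probes joined across array designs by their listing. Because of their opposite labels the 192 h replicates were fitted exactly. The spread in this fit therefore came from 18 h and 72 h alone, and the count at 192 h does not reflect the spread at that time. This fit takes its dye coefficient from 192 h alone, the only time at which the polyA replicates have opposite labels. An error in that coefficient would enter the other times with the sign turned. Over probes the 18 h and dye coefficients correlated -0.68. However, the 18 h coefficient is here the 18 h mean minus the dye coefficient. That favours a negative correlation with or without such an error, so the value cannot decide. A response shared by 18 h and 72 h also remains open. The 18 h mean correlated 0.59 with the 72 h mean and 0.08 with the unturned 192 h replicate 2, a difference of -0.51. However, 18 h and 72 h also share dye labels and array design, whereas the 192 h arrays lie on other designs. Probes of 192 h were matched to those of 18 h only by names not borne out. The lower value could come from that matching alone, so the difference cannot decide. Under the same matching the 18 h mean correlated 0.25 with 192 h replicate 1, labelled alike. That replicate correlated -0.24 with the turned replicate 2, which includes an array of a further design. The 192 h replicates thus did not share a direction over the listed probes. The data do not separate these explanations.

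On 15 polyA arrays the brightness of a spot did not follow its listed gene. Against noise stands that spot brightness correlated 0.49 (median, by rank) between arrays of the same design. Against another spot order or layout stands that the highest absolute rank correlation with the total RNA arrays over 3840 combinations of spot order and layout and 601 shifts was 0.115. A listing that belongs to another print, or a signal that does not follow transcript abundance, may remain, and neither was tested. No biological explanation was tested.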

How the results depend on the processing

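The main counts are 0 called genes for each time, the mean and the difference between times, and 0 shifted lists for each time and the mean. The probe sets with fewer replicates and the unturned ratios were added after seeing the data. Over all alternatives 27 of 31 gave 0 called genes at 18 h, 30 of 31 at 72 h, 30 of 31 at 192 h, 28 of 31 on average and 30 of 32 for the difference between times. The filter on dim probes removed no probe, so leaving it out tests nothing. The fits over all 32 arrays, with and without a dye covariate, join total RNA probes to polyA arrays by names not borne out. Their counts of 0 called genes therefore say little.

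The polyA arrays alone with a dye covariate called 202 genes at 18 h, 189 at 72 h, 256 at 192 h and 413 on average, under names not borne out. The spread in that fit came from 18 h and 72 h alone. Within 1 of the array designs, with a single 18 h replicate assumed to vary like the others, 38 genes were called at 18 h, 5 on average (Snx20, Caap1, Rfng, Dctpp1 and Parp9, named after their values were seen, with -3.98 to -3.01 in that replicate) and 13 for the difference between times. With at least 5 of 8 replicates the counts were 14, 6 and 10. All 14 were measured in 18 h replicate 4 and not dye-balanced in replicate 3. In replicate 4, 112 of 5912 probes had a log2 ratio under -1, 94 of them in print grids 1 to 8 of 48, with a median of -3.28 on the array with tumour in Cy5 and -0.08 on its dye-swapped partner. With at least 2 replicates at each time limma called 0 genes at 18 h, with 91 of 2198 probes at an unadjusted p under 0.05. Leaving out each replicate gave 0 to 1 genes at 18 h, the 1 being Ptpmt1 without 18 h replicate 3.

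Gene lists passed as follows. At 18 h there were 2 with median centring, 1 with the first read alone, 2 with the authors' values, 2 with at least 5 replicates and 3 with at least 2 per time. At 72 h there were 2 with print-tip loess, 2 with median centring, 1 with both channels over background, 2 within each array design, 1 with the replicate block and 1 with the authors' values. At 192 h there was 1 with the first read alone. On average there were 1 without background correction, 2 with median centring and 1 with at least 2 replicates per time. Leaving out each replicate gave 0 to 1 lists at 18 h (1 without 192 h replicate 4), 0 to 3 at 72 h (2 without 72 h replicate 3, 2 without 72 h replicate 4 and 3 without 192 h replicate 5) and 0 to 2 on average (1 without 72 h replicate 3 and 2 without 72 h replicate 4). Of these 37 calls 4 held with an estimated correlation, and oxidative phosphorylation and ribosomal proteins at 18 h had adjusted p = 0.321 and 0.624 with at least 2 replicates per time. Median centring moved the median of all tested genes to -0.11 at 18 h and -0.20 at 72 h. The ribosomal list at 72 h passed in opposite directions within the 2 array designs, each with a single 72 h replicate, with adjusted p = 0.875 and adjusted p = 0.998 with an estimated correlation.

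The replicate block was fitted on the numbers 3 and 4 shared between times and called 0 genes and 1 list, heat shock genes at 72 h (adjusted p = 0.0276, or adjusted p = 0.923 with an estimated correlation). Differences between numbers 3 and 4 correlated over probes by -0.24, 0.07 and -0.24 between times, and at 18 h and 72 h these numbers are also the array designs. The correlation of total RNA and polyA ratios averaged over times was -0.116, with -0.063 at 192 h alone and -0.0403 with the polyA arrays of title number 2 at 18 h and 72 h turned in case it marks the swapped dye. Of 993 values of named genes under alternatives fixed before the data were examined, 23 changed sign and 3 passed. The need for an intensity above 0 in both channels limits the test: 1008 of 9008 accessions had a ratio on both arrays of all 8 replicates. On a total RNA array up to 63.3% of spots had an intensity in channel B only, and up to 41.5% in channel A only. A transcript with signal in only 1 of the compared groups would thus not have been tested.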

Other observations

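The tests of the dye labels and of the probe sets were chosen only after the results were seen, and those of the sign patterns before. Among 2198 probes with at least 2 replicates at each time, the list of cytokine and inflammatory genes was shifted upwards on average over the times (limma camera, adjusted p = 0.00533, or adjusted p = 0.0129 with an estimated correlation). All 7 measured genes lay above 0, with a median log2 ratio of 0.12, and 0 of them passed alone. Il6ra, a subunit of the interleukin 6 receptor, had 0.27 ± 0.15 (SE), above 0 in 4 of 7 replicates, Cebpb, a transcription factor of the acute phase, 0.15 ± 0.09 in 5 of 7, Irak1, a kinase of interleukin 1 signalling, 0.12 ± 0.07 in 5 of 7 and Cxcl12, a chemokine, 0.15 ± 0.11 in 4 of 6. With print-tip loess on the same probes the list did not pass on average over the times (adjusted p = 0.0920, median 0.09). At 18 h it had adjusted p = 0.0749 with print-tip loess, and with loess over the whole array it had adjusted p = 0.0436, or adjusted p = 0.154 with an estimated correlation. Among the 3985 probes with at least 5 of 8 replicates, 10 genes of the list were measured, with a median of 0.07 on average and adjusted p = 0.329. The adjusted p on average over the times ran from 0.00533 to 0.538 over the 4 settings without polyA arrays in which the list had at least 5 genes. Among the 1008 probes it had 2.

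The ratios of channel B over channel A of the 2 arrays of a replicate, labelled with opposite dyes, ran the same way, with a mean r of 0.31. Arrays of different replicates within a design had a mean r of 0.215, so much of this was not particular to pairs. A gene-specific dye effect may account for part of this, since the mean ratio per probe correlated 0.319 between the 2 array designs. If instead both arrays of a pair had been hybridised in one orientation, tumour values would cancel in their mean. Arrays of a pair also carry neighbouring numbers in their titles, and what part this had in their correlation was not tested. The labelled pairs correlated more than most other pairings of the arrays within a design, with 389 of 11025 pairings as high (exact share 0.0353), as a shared orientation needs. Left unturned and centred by design, replicates of one time correlated at -0.0034 on average and those of different times at 0.0009, where it needs a difference unless the response is alike at all times, so that the orientation of the pairs stays open.

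Since limma called 0 probes, the count at an unadjusted p under 0.05 was set against that with the signs of replicates turned. At 192 h the count was 47, the highest of the other sign patterns gave 52, and 3 of 8 patterns gave as many, which are too few patterns for a share under 0.05. For the mean over the times the count was 31, 36 of 100 patterns gave as many, and the highest other gave 87, so chance could not be excluded.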
